A study of Homo sapiens with 3 samples.

How the data were processed

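Gene expression was measured by sequencing of total RNA from C4-2, a prostate adenocarcinoma line derived from LNCaP. The 3 libraries were labelled as replicates of unmodified C4-2 cells, and all 3 fell into 1 group. The labels did not say whether the replicates came from separate cultures, so a p-value here measures only the spread between these libraries, which may be technical. The series also describes neuroendocrine lines and knockdown of neuropilin-2 in neuroendocrine cells; those samples were not analysed here, so no comparison between groups was made.

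Per the labels' protocols, RNA was extracted with Trizol, cleaned on silica columns and depleted of ribosomal RNA, with 770 ng of RNA as input. Libraries were built with the strand-specific NEBNext Ultra II Directional kit. Per the submitters' processing notes, the reads were handled with FastQC, Trim Galore, STAR 2.7.0f, Subread 1.6.3 and DESeq2 1.26.0, on the GRCh38 build. Per the file headers, the deposited values were raw counts of reads per gene from featureCounts 1.6.3, summed over the exons of 58302 Ensembl release 90 genes. The recorded options named only the annotation, the output and the number of threads. With those options featureCounts ignores strand, drops reads that map to several places, drops reads that overlap exons of more than 1 gene, and counts each mate of a pair by itself. A gene with an overlapping or antisense neighbour, or with a near-identical copy, can therefore be undercounted or share reads with its neighbour. No normalisation was applied to the deposited counts, and whether the libraries were read from both ends was not given in the sources used here.

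The libraries held 51200272, 47513470 and 49965601 assigned reads in replicates 1, 2 and 3. A count of 3 reads, the upper limit that a count of 0 allows, equalled 0.0631 CPM, a count scaled by library size, in the smallest library. If both mates of each fragment were counted, the limit is 6 reads, or 0.126 CPM. Intervals and limits of this kind cover counting error only, because reads carry no molecular identifiers. Gene names and biotypes came from GENCODE release 44, matched by Ensembl identifier: 57532 of 58302 identifiers (98.7%) matched, and the 770 others held 0.210% of reads. The length column of the files equalled the merged exon length in 58302 of 58302 genes. Exon GC content could be computed for 58243 genes (99.90%) from the hg38 sequence.

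TPM, transcript abundance scaled by exon length and library total, was computed from the deposited counts and these exon lengths over all genes of a library. A gene was called detected with at least 10 reads in every library. Log2 values were taken as log2(TPM + 0.1), which understates the distance of low genes from high ones. The 32 gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The level of a list was the median log2(TPM + 0.1) of its members. It was set against 10000 random lists of the same size, drawn from 19708 protein-coding genes and matched on exon length in 10 bins. A list was called higher above the 97.5th percentile and lower below the 2.5th percentile of the random lists, as a description of these libraries and not as a p-value across samples. The histone and mitochondrial lists hold short genes, and matching on length set them against a mostly silent pool. Lists of non-coding RNAs were not placed.

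Variation between libraries was tested per gene by a chi-square test of homogeneity of the 3 counts against TMM effective library sizes, with Benjamini-Hochberg adjustment over detected genes and a threshold of 0.05. TMM factors and the common biological coefficient of variation came from edgeR 4.0.16 in R 4.3.3. The variation of a list was the median SD of log2 CPM (prior count 2) over its detected members, set against 10000 random lists matched on mean expression in 20 bins. Differences within a library between lists or genes were tested by an exact two-sided sign-flip permutation test over the 3 libraries, whose smallest possible p is 0.25, so no such test could pass 0.05. All other computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

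The variation test was tested on simulated data for these libraries, with 200 of 21039 genes changed. The changed genes were drawn from those with a mean of at least 100 reads, so recovery at lower counts was not tested. Reads were simulated as independent, so the rates do not cover libraries in which both mates of a fragment are counted. Without extra spread, it recovered 82.5% of genes changed 1.25-fold and 100% of genes changed 2-fold, and called 0.01% and 0.05% of unchanged genes. With a simulated coefficient of variation of 0.1 in all genes, the estimate was 0.1 with the 1.25-fold and 0.111 with the 2-fold changes, and 47.1% and 46.8% of genes without a planted change were called, since those genes then vary beyond counting noise. The list test was run on 40 random lists of 20 genes per planted shift. With no shift it called 0 lists higher and 3 lower. With log2 shifts of 1.5, 3 and 5 it called 14, 25 and 38 of the 40 lists higher, so a list that was not called can still differ from other genes.

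The text names NRP2 and the genes of every single-gene contrast, the 4 members of each list with the highest mean TPM (2 for absent cell types and unrelated tissues), every neuroendocrine marker and every neuropilin list member, MSH6, RB1, JAK1 and some other tumour suppressors, the 15 protein-coding nuclear genes with the highest TPM, and the 10 most variable genes with a mean of at least 100 reads. Some genes that this rule names, and a contrast that needs such a gene, are not reported here. Any other gene was chosen after its values were seen, and the text says so beside it. Alternatives changed the pseudocount, length scaling, TPM denominator, read minimum, normalisation (DESeq2 1.42.0 size factors or total counts), dispersion tool, background genes and list summary, and left out each replicate in turn. Alternatives for the counting of mates, for trends with exon length and GC content, and for overlapping exons were added after seeing the data.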

Results

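The series asked how prostate adenocarcinoma cells differ from neuroendocrine-like cells in gene expression, and what depletion of neuropilin-2 does to the latter. The 3 libraries described here are replicates of C4-2, an adenocarcinoma line derived from LNCaP. They held 47513470 to 51200272 reads assigned to genes. In all, 21039 genes reached 10 reads in every library, 14153 of them protein-coding and 3818 long non-coding. A mean of at least 1 TPM was reached by 21283 genes, 12366 of which were among the 19708 protein-coding genes, and 2579 protein-coding genes (13.1%) had 0 reads in all 3 libraries, among them all 252 whose exon bases are fully shared with another gene. Values below are mean TPM ± SD over n = 3 libraries unless stated otherwise.

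C4-2 cells expressed the androgen response program at high levels. All 28 members of the androgen response list were detected, and all 28 lay at 1 TPM or more. The prostate-specific antigen gene KLK3 reached 1439.7 ± 26.3 TPM, the prostein gene SLC45A3 469.7 ± 12.0 and the lipid phosphatase gene PLPP1 339 ± 6.44, and PLPP1 shares 28.4% of its exon bases with another gene. The list median was 3.87 log2 units above that of length-matched random lists, at the 100th percentile. KLK3 is annotated on chromosome 19 (50854915 to 50860764, plus strand) of GRCh38.

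Neuroendocrine markers were mostly low. Of 24 markers, 12 were detected and 6 reached 1 TPM: DDC, which encodes the aromatic amino acid decarboxylase, at 75.6 ± 5.90 TPM, the enolase gene ENO2 at 12.3 ± 0.366, UCHL1 at 6.79 ± 0.510, SCG5 at 2.82 ± 0.408, the chromogranin gene CHGA at 2.53 ± 0.336 and the synaptophysin gene SYP at 2.29 ± 0.312. INSM1, SCG3, NCAM1, CELF3, SYT1 and PCSK1 were detected between 0.267 and 0.495 TPM. TH, CHGB, SVOP, SCG2, SNAP25, SRRM4, PCSK2, CALCA and SCN3A held at most 18 reads in any library. ELAVL4, GRP and SST had 0 reads in every library, which allows up to 0.0631 CPM in the smallest, or 0.126 CPM if both mates of each fragment were counted. The list median, at −4.41 log2 units against random lists, was called lower (0.22nd percentile).

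Within each library, the androgen response list exceeded the neuroendocrine list by 8.60 ± 0.103 log2 units (SD, n = 3), or 388-fold, and by 6.54 to 9.12 log2 units over the alternatives. The direction was the same in 3 of 3 libraries (exact sign-flip p = 0.25, the smallest that 3 libraries allow). Genes of tissues unrelated to prostate served as background, and the neuroendocrine median lay 1.51 ± 0.245 above theirs (exact sign-flip p = 0.25, 3 of 3 libraries). That difference turned to −0.48 when only detected members of both lists were compared. In the background list 6 of 30 genes were detected, led by the myelin gene MBP at 11.8 ± 0.389 TPM and the luteinising hormone gene LHB at 6.04 ± 1.47, and its median was called lower at −2.80 log2 units against random lists (0.46th percentile).

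**Figure D1:**
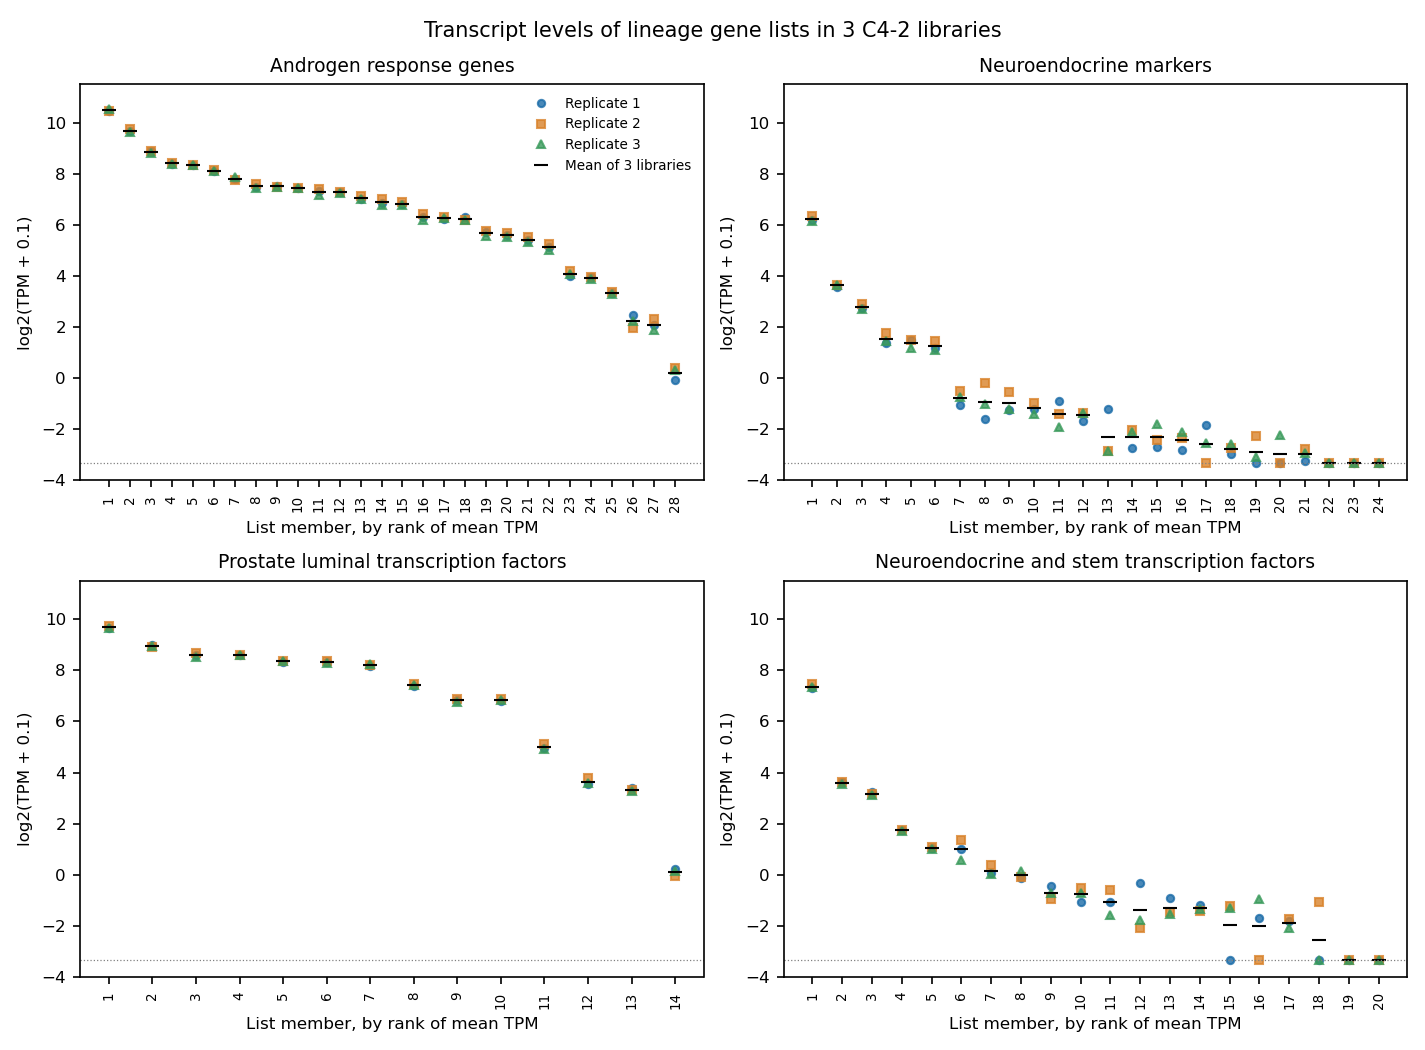
Transcript levels, as log2(TPM + 0.1), of the members of 4 lineage gene lists in C4-2 cells, ordered within each list by mean TPM. Points are the 3 libraries, black bars their mean, and the dotted line marks 0 TPM. All 28 androgen response list members lay at 1 TPM or more, against 6 of 24 neuroendocrine markers.

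Luminal transcription factors were abundant, and fewer of the neuroendocrine and stem factors were detected. All 14 luminal factors were detected, among them SPDEF (495 ± 8.71 TPM), EHF (389 ± 22.9) and the pioneer factor gene FOXA1 (386 ± 2.57). Of 20 neuroendocrine and stem factors, 13 were detected and 7 reached 1 TPM, led by HES6 at 165 ± 8.96, ONECUT2 at 12.0 ± 0.509, LHX2 at 8.87 ± 0.329 and POU4F1 at 3.23 ± 0.0184. POU4F1 shares 27.7% of its exon bases with another gene. The luminal list lay 4.86 log2 units above random lists (100th percentile), whereas the neuroendocrine and stem list, at −3.04, was not called (4.68th percentile), and among detected genes alone it was called lower at −3.85. The luminal factors exceeded the others by 8.59 ± 0.105 log2 units in 3 of 3 libraries (exact sign-flip p = 0.25).

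NRP2, the gene under study, was detected at a low level in C4-2 cells. It encodes a co-receptor for semaphorins and for vascular endothelial growth factors, and it had 54, 70 and 34 reads, or 0.235 ± 0.0903 TPM, at the 27.4th percentile of protein-coding genes. Its paralog NRP1 reached 13.1 ± 0.563 TPM. The difference of NRP2 minus NRP1 was −5.34 ± 0.339 log2 units, of the same sign in 3 of 3 libraries (exact sign-flip p = 0.25). Over the alternatives it ranged from −5.81 to −3.52. NRP2 lay 1.63 ± 0.518 above the median of unrelated-tissue genes (exact sign-flip p = 0.25, 3 of 3 libraries), and the difference turned to −2.42 when only detected background genes were counted. The counts of NRP2 varied beyond sampling noise (chi-square test, adjusted p = 0.00409), which did not hold when the statistic was divided by 2 (adjusted p = 0.123), a check for mates counted separately. NRP2 is annotated on chromosome 2 (205681990 to 205798133, plus strand) and NRP1 on chromosome 10 (33177492 to 33336262, minus strand).

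Other genes of the neuropilin axis spanned a wide range. Of 20 neuropilin, plexin and semaphorin genes, 17 were detected and 13 reached 1 TPM. The plexin gene PLXNB2 was highest at 241 ± 5.54 TPM, followed by SEMA3C, which encodes a secreted neuropilin ligand, at 54.7 ± 2.32, PLXNA1 at 40.9 ± 1.83 and PLXNB3 at 33.7 ± 1.36, which shares 20.4% of its exon bases with another gene. SEMA3F, PLXNB1, PLXNA3, SEMA4D, SEMA6A, SEMA3G and SEMA3B lay between 6.60 and 24.7 TPM, and PLXNC1, PLXND1 and PLXNA2 between 0.916 and 1.08. SEMA3A was at 0.162 ± 0.104 TPM, and SEMA3D, SEMA3E and PLXNA4 were at 0.0792 ± 0.0991, 0.0487 ± 0.0448 and 0.0353 ± 0.0181. The list was not called, with its median at the 49.96th percentile of random lists.

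Members of the vascular endothelial growth factor list differed widely in level. VEGFB reached 41.9 ± 3.22 TPM, VEGFA 39.4 ± 0.799, NRP1 13.1 ± 0.563 and the receptor gene FLT4 1.71 ± 0.0960, and KDR, named after its values were seen, had 0 reads. VEGFC had 10, 4 and 12 reads (0.217 ± 0.0982 TPM) and was not detected. VEGFA exceeded it by 7.01 ± 0.519 log2 units in 3 of 3 libraries (exact sign-flip p = 0.25), and by 5.06 to 9.47 over the alternatives. Of 10 members 7 were detected, and the list, at −3.58 log2 units against random lists, was not called (4.21st percentile).

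**Figure D2:**
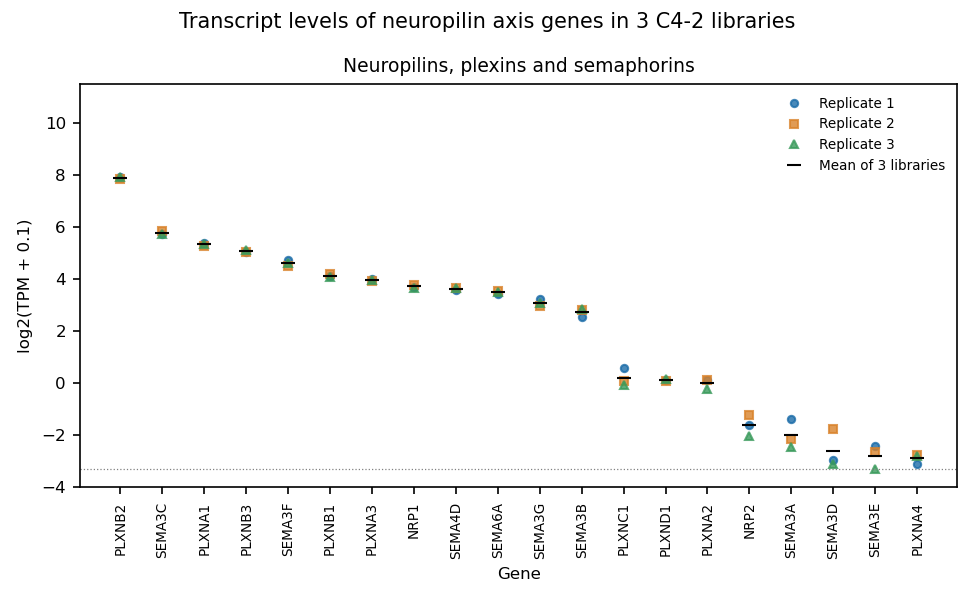
Transcript levels, as log2(TPM + 0.1), of 20 neuropilin, plexin and semaphorin genes in C4-2 cells. Points are the 3 libraries, black bars their mean, and the dotted line marks 0 TPM. The difference of NRP2 minus NRP1 was −5.34 log2 units, and −5.81 to −3.52 over the alternatives.

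Most genes of regulated exocytosis were detected, and fewer of the cytokines and growth factors. Of 27 genes of regulated exocytosis, 25 were detected, with the small GTPase genes RAB3D at 202 ± 6.25 TPM and RAB3A at 83.9 ± 3.19, VAMP8 at 101 ± 7.03 and the synaptotagmin gene SYT4 at 72.1 ± 7.83. RAB3D shares 24.9% of its exon bases with another gene. Of 31 secreted cytokines and growth factors, 18 were detected, with GDF15 at 323 ± 4.85 TPM, MDK at 119.6 ± 3.06, IGF1 at 10.7 ± 0.553 and EGF at 7.24 ± 0.387. IGF1 shares 82.8% of its exon bases with another gene, so its value is uncertain. IL6, named after its values were seen, had 0 reads. Neither list was called: their medians were at 1.00 (89.5th percentile) and −2.40 (6.20th percentile) log2 units against random lists.

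C4-2 cells carried a luminal epithelial profile. All 18 luminal markers were detected, among them the junction gene JUP at 363 ± 8.71 TPM, the keratin gene KRT18 at 324 ± 12.7, the protease gene ST14 at 288 ± 2.75 and the claudin gene CLDN3 at 275 ± 11.7. Of 15 basal markers 9 were detected, led by ITGA6 at 16.7 ± 2.12 TPM, ITGB4 at 4.69 ± 0.0911, DST at 2.40 ± 0.153 and KRT14 at 1.01 ± 0.121. TP63 and KRT5, named after their values were seen, had 0 reads. The luminal list lay 4.27 log2 units above random lists (100th percentile) and the basal list was called lower at −4.49 (0.84th percentile), a call that was lost at −3.89 without matching on exon length. Luminal exceeded basal markers by 8.45 ± 0.0380 log2 units in 3 of 3 libraries (exact sign-flip p = 0.25).

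Mesenchymal markers ranged widely, with the fibronectin gene FN1 the highest. FN1 reached 155 ± 0.917 TPM, the transcription factor genes SNAI1 and SNAI2 7.60 ± 0.805 and 6.47 ± 1.09, and the vimentin gene VIM 6.94 ± 0.537. VIM shares 24.4% of its exon bases with another gene. Of 14 members 10 were detected, and the list, at −2.59 log2 units against random lists, was not called (10.9th percentile), but was called lower among detected genes at −3.10. Luminal exceeded mesenchymal markers by 7.39 ± 0.263 log2 units in 3 of 3 libraries (exact sign-flip p = 0.25).

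Few markers of cells foreign to the culture were detected. Of 19 fibroblast, smooth muscle and endothelial markers 7 were detected, with the collagen gene COL1A1 at 10.2 ± 0.392 TPM and VWF at 3.68 ± 0.191, and the list was called lower at −5.38 log2 units against random lists (0.01st percentile). Of 21 blood and immune markers 5 were detected, with NKG7 at 2.56 ± 0.184 TPM and CD8A at 1.84 ± 0.492, and the list, at −2.36, was not called (7.13th percentile).

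NR3C1, the glucocorticoid receptor gene, lay at 0.462 ± 0.119 TPM, the 31.9th percentile of protein-coding genes. Among 17 nuclear receptors, 15 were detected, among them ESRRA (144 ± 5.81 TPM), RXRA (65.8 ± 0.173) and NR2F2 (40.7 ± 0.670). Of 25 steroid metabolism genes 16 were detected, led by HSD17B10 at 373 ± 2.16 TPM, HSD17B4 at 67.3 ± 3.93, HSD11B2 at 48.8 ± 0.499 and the 5-alpha reductase gene SRD5A1 at 21.2 ± 1.28. Neither list was called, at 0.45 (70.6th percentile) and −1.41 (22.1st percentile) log2 units against random lists.

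Genes of lipid and cholesterol synthesis were all detected at 1 TPM or more. Of these 25 genes, the fatty acid synthase gene FASN reached 1271 ± 17.8 TPM, the citrate lyase gene ACLY 457 ± 8.66 and ELOVL5 433 ± 27.4. All 21 protein folding genes likewise reached 1 TPM, with the endoplasmic reticulum chaperone genes CALR at 1722 ± 27.3 TPM, HSPA5 at 954 ± 27.4, PDIA4 at 627 ± 19.8 and HSP90B1 at 577 ± 26.6. All 20 hypoxia and glycolysis genes were detected, and ENO1 reached 1811 ± 22.6 TPM, GAPDH 1775 ± 69.2, ALDOA 797 ± 18.9 and LDHA 505 ± 27.9. These lists lay 2.42, 4.06 and 3.17 log2 units above random lists, each at the 100th percentile.

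Proliferation genes were abundant, as were chromatin regulators. All 31 proliferation genes reached 1 TPM, with MYBL2 at 475 ± 19.3, PCNA at 387 ± 15.6, the helicase gene MCM7 at 368 ± 12.3 and CDC20 at 287 ± 6.91. All 23 chromatin regulators reached 1 TPM, with the lamin gene LMNB1 at 272 ± 12.2, HDAC1 at 166 ± 9.60, the maintenance methyltransferase gene DNMT1 at 135 ± 0.868 and CBX2 at 129 ± 2.05. Their medians lay 4.06 and 2.65 log2 units above random lists, each at the 100th percentile.

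All 19 tumour suppressor and mismatch repair genes were detected at 1 TPM or more. The cell cycle inhibitor genes CDKN1A and CDKN1B lay at 104 ± 0.532 and 67.2 ± 3.92 TPM. The mismatch repair gene MSH6 lay at 26.5 ± 1.07 TPM, RB1 at 23.4 ± 2.45 and JAK1 at 5.52 ± 0.176. The list median lay 1.49 log2 units above random lists (98.5th percentile). Transcript levels carry no information here on whether the encoded proteins are intact.

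Surface antigens and resistance genes were led by prostate lineage genes and chaperones. FOLH1, which encodes prostate-specific membrane antigen, reached 425 ± 28.2 TPM, STEAP1 384 ± 37.8, STEAP2 272 ± 24.9 and KLK2 175 ± 1.63, and 15 of 17 surface targets were detected. Of 20 efflux and resistance genes 20 were detected, with HSPB1 at 2032 ± 107 TPM, HSP90AA1 at 882 ± 33.4, MYC at 292 ± 5.01 and the transporter gene ABCC4 at 185 ± 11. Neither list was called, at 1.61 (95.5th percentile) and 0.37 (65.0th percentile) log2 units, and the second value turned to −0.52 among detected genes.

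The immediate early and stress list was led by MYC, JUND (262 ± 7.31 TPM), HSPA1B (183 ± 0.284) and JUNB (111 ± 1.24), with 19 of 20 members detected. HSPA1B has a near-identical copy, HSPA1A (1.27 ± 0.244 TPM, named after its values were seen), so the split between them is uncertain. Of 25 interferon response genes 24 were detected, led by HLA-C at 241 ± 3.42 TPM, ISG15 at 139 ± 9.90 and B2M at 59.6 ± 3.96. Neither list was called, at 1.93 (90.1st percentile) and −1.01 (27.1st percentile) log2 units, and the first turned to −0.16 among detected genes.

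The ETS genes that are rearranged in many prostate tumours were low except for ELK4. ELK4 lay at 51.3 ± 4.17 TPM, ETV4 at 1.07 ± 0.288, ETV5 at 0.141 ± 0.0217 and FLI1 at 0.0651 ± 0.0367. ETV1 and ERG, named after their values were seen, had 12, 12 and 0 reads and 0 reads in every library. The list was called lower at −5.64 log2 units against random lists (0.47th percentile). Of 19 long non-coding RNAs linked to prostate cancer, 16 were detected, with MALAT1 at 1570.2 ± 172 TPM, SNHG1 at 51.4 ± 2.86, NEAT1 at 24.8 ± 1.48 and CTBP1-AS at 19.98 ± 2.23. CTBP1-AS shares 20.8% of its exon bases with another gene.

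Transcripts without a poly(A) tail, housekeeping genes and mitochondrial genes held the highest TPM values. Mitochondrially encoded genes took 3.17 ± 0.256% of reads, with MT-CO2 at 13517 ± 1809.8 TPM, MT-ATP6 at 12616 ± 242, MT-CO1 at 11899 ± 715 and MT-CO3 at 11096 ± 717. The replication-dependent histone list took 0.524 ± 0.0253% and the small structural RNA list 1.66 ± 0.0827% of reads. RN7SL2, an RNA of the signal recognition particle, took 1.61 ± 0.0724% of reads and 16.3 ± 0.666% of TPM, at 162957 ± 6665 TPM. It has near-identical copies, and reads that map to several of them would have been dropped by the counting. Of the 15 small structural RNAs in the files, 6 were detected and 5 had 0 reads, each of the 5 with all exon bases shared with another gene. SNORA73B, SNORD3A and RNU4-2 lay at 1548 ± 484, 1509.7 ± 309 and 1444 ± 354 TPM. Protein-coding genes took 95.4 ± 0.0924% of reads, long non-coding genes 1.84 ± 0.0636% and the 20 most abundant genes 7.88 ± 0.271%.

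Histone and translation genes were prominent among the 15 protein-coding nuclear genes with the highest TPM, counted over identifiers matched in GENCODE release 44. They were H2BC12 (4349 ± 465 TPM), H1-2 (3866 ± 87.7), EEF2 (3462 ± 106), CKB (3225 ± 103), ACTB (3169.9 ± 115), H1-4 (3125 ± 215), H1-5 (2863 ± 94.4), RPL7A (2491 ± 40.3), RPS2 (2436 ± 103), EEF1A1 (2427 ± 99.7), RPL13A (2225 ± 58.5), RPS18 (2112 ± 44.1), H2AC20 (2038 ± 57.6), HSPB1 (2032 ± 107) and ATP5F1B (2002 ± 32.0). RPS2 shares 25.6% of its exon bases with another gene, and many ribosomal and histone genes have close copies that can take or lose reads. All 28 ribosomal protein genes, 19 of 20 histone genes and all 13 mitochondrial protein genes were detected. Ribosomal protein genes, where RPL8 followed at 1937 ± 63.9 TPM, histone genes and mitochondrial genes lay 7.23, 11.69 and 15.77 log2 units above random lists, each at the 100th percentile. Of the 30 lists placed, 12 were called higher and 5 lower.

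Mitochondrial, histone, ribosomal and small structural RNA genes varied more between libraries than genes of like expression. The median SD of log2 CPM was 3.11 times that of matched random lists for the mitochondrial list, 6.24 times for small structural RNAs, 1.595 times for histones and 1.42 times for ribosomal proteins. These 4 of the 32 lists were called more variable and 0 less variable. With the GC trend removed all 4 were called more variable at larger ratios. These were 4.92 for the mitochondrial list, 8.25 for small structural RNAs, 2.08 for histones and 2.14 for ribosomal proteins. The ratios grew mainly because the matched genes varied less, with a median SD of 0.0310 in place of 0.0470 for the mitochondrial list. The SD of the lists themselves fell from 0.0913 to 0.0848 for histones and from 0.0670 to 0.0663 for ribosomal proteins. It rose from 0.146 to 0.152 for the mitochondrial list and from 0.388 to 0.398 for small structural RNAs. Without replicate 2, the small structural RNA list alone kept that call, and the mitochondrial ratio was 1.36, the histone ratio 0.75 and the ribosomal ratio 0.80. The small structural RNA ratio was 2.24 without replicate 3, the histone call was also lost without replicate 3 (90.7th percentile) and with the length trend removed (95.5th), and the ribosomal call without replicate 1 (97.3rd), with total counts (97.1st) and with the length trend removed (95.5th). The androgen response list (ratio 0.954), neuroendocrine markers (0.830) and neuropilin genes (1.13) were not called.

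Among genes with a mean of at least 100 reads, the mitochondrial ribosomal RNAs had the largest spread. MT-RNR2 had 274, 904 and 202 reads (adjusted p = 1.0e-149) and MT-RNR1 144, 476 and 146 (adjusted p = 7.8e-66). SNORA74B, TNFRSF10C, RNU5A-1, RALGAPA1P1, CATSPERB, SLITRK6, PPP1R26P1 and ENSG00000275966 followed, with SDs of 0.67 to 0.75 on the log2 CPM scale and adjusted p between 1.3e-15 and 1.2e-06. All 10 kept an adjusted p below 0.05 after the statistic was divided by 2.

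Across all genes, 9694 of 21039 tested (46.1%) varied beyond counting noise by the chi-square test, which takes each read as an independent count. The common biological coefficient of variation was 0.0737. Pairs of libraries differed in 5180, 5201 and 7096 genes, and in 1453, 1294 and 3260 genes with the statistic divided by 2, so no pair agreed within sampling noise, and no pair had equal counts in every gene. The count of varying genes was 3699 (17.6%) when the statistic was divided by 2, as would apply if both mates were counted. It was 1927 (9.16%) with the trend with GC content removed as well. With the undivided statistic it was 5187 without replicate 2 and 5182 without replicate 3.

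Genes of low and of high GC content moved apart between libraries. Over 7930 genes with a mean of at least 1000 reads, the log2 difference of replicate 2 minus replicate 3 correlated with exon GC content across genes (r = −0.646, rho = −0.680), where genes are not independent replicates. Its median was 0.14 in the tenth of genes with the lowest GC content and −0.11 in the tenth with the highest.

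**Figure D3:**
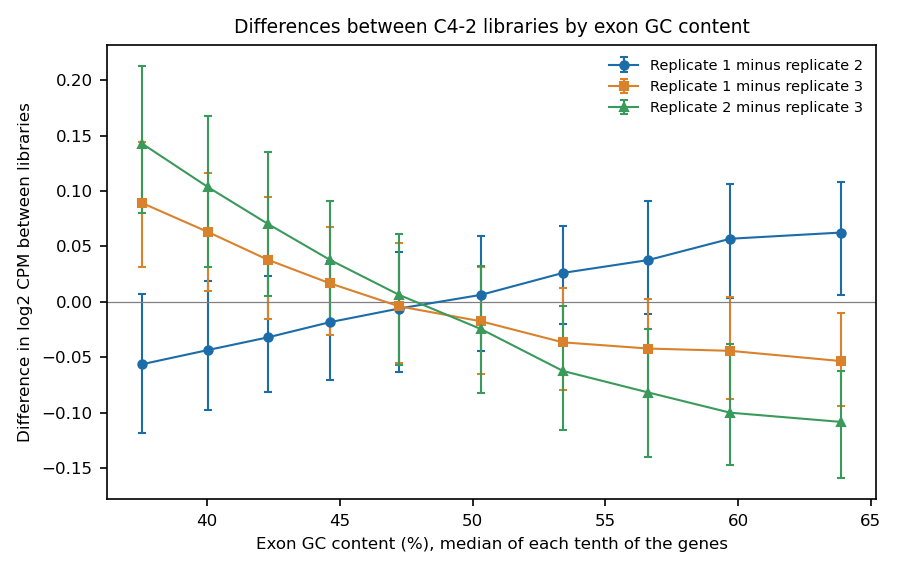
Difference in log2 CPM between pairs of C4-2 libraries by exon GC content, in 10 equal bins of 7930 genes. Points are medians over genes and bars the interquartile range. Replicate 2 minus replicate 3 ran from 0.14 at the lowest GC content to −0.11 at the highest.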

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

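A histone locus stood out among data outside the comparisons. ENSG00000274267 carried no gene name in GENCODE release 44 and belonged to no list, yet it reached 4846 ± 249 TPM (SD, n = 3), with 34881, 28933 and 33711 reads. It was singled out as the identifier with the highest mean TPM among the 770 without a match in release 44, which no comparison used. Its high level therefore follows from the way it was picked. It lay above 0.0631 CPM, the limit that a count of 0 allows in the smallest library. It lies on chromosome 6 (26031650 to 26032060, minus strand) of GRCh38, where release 44 places the histone H3 gene H3C2. H3C2 was a member of the histone list that no identifier of the files matched.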

How the results depend on the processing

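The alternatives for mate counting, for length and GC trends and for overlapping exons were chosen after seeing the data. Of 1213 alternative values over 234 results, 1011 were labelled the same, 10 weaker, 8 stronger, 176 moved and 8 reversed. For contrasts the label rested on direction, and for list levels and list variation on direction and call. Counts and TPM values of single genes have neither, and were labelled moved when they changed by more than a fixed fold limit. Of the 179 named genes, 163 moved, all under TPM over protein-coding nuclear genes, which raised TPM 1.51-fold, 1.51-fold and 1.54-fold in replicates 1, 2 and 3. That change scales all genes of a library by the same factor, just above the fold limit. These moves therefore follow from the choice of denominator and carry no information on the stability of single genes. List levels kept direction and call in 284 of 300 alternatives, and 73 of 75 alternatives kept the direction of the 9 contrasts. Many of those 75 could hardly have changed a direction. Each contrast had the same sign in 3 of 3 libraries, so leaving out a replicate could not reverse it. Changes of pseudocount or TPM denominator keep the order of genes within a library. The sizes of the contrasts moved more: NRP2 minus NRP1 ranged from −5.81 to −3.52 log2 units, VEGFA minus VEGFC from 5.06 to 9.47, luminal minus basal from 6.69 to 8.84, luminal minus mesenchymal from 6.22 to 7.58, and luminal minus neuroendocrine and stem factors from 6.88 to 8.88. Limited to detected genes, the neuroendocrine and stem factors were called lower at −3.85 and mesenchymal markers at −3.10, 8 lists were placed lower, and drug efflux (−0.52) and immediate early genes (−0.16) reversed. With detected members only, NRP2 minus unrelated-tissue genes was −2.42 and neuroendocrine markers minus those genes −0.48, the low ends of ranges that reached 4.17 and 4.01. Without length matching, the neuropilin list lay at 0.93 and the basal list, no longer called, at −3.89. Leaving out a replicate moved the neuropilin list between −0.0315 and 0.0493. Lists varying more numbered 2 with the length trend removed and 1 to 4 with a replicate left out. Lists varying less numbered 1 at a minimum of 50 reads, 2 with the GC trend removed and 0 to 1 with a replicate left out. With a replicate left out, the variation ratio was 0.75 to 1.80 for histones and 0.80 to 2.25 for ribosomal proteins, the low end without replicate 2. Blood and immune markers were called more variable without replicate 1 (ratio 2.68). By tagwise dispersion, a different measure, the mitochondrial ratio was 1.11 and the small structural RNA ratio 1.63, both called. The histone ratio of 1.06 and the ribosomal ratio of 1.01 were called as well, so under this measure a small ratio can be called. TPM over protein-coding nuclear genes put 12939 genes at 1 TPM or more, since only those genes enter it. Genes varying numbered 5182 to 7087 with a replicate left out, where fewer samples enter the test, 3699 with the statistic divided by 2, and 1927 with the GC trend removed as well. Where no reason is given, the cause was not tested. No paired analysis was possible because the libraries form 1 group. Depth limits genes below 0.0631 CPM, or 0.126 CPM if both mates were counted.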

Other observations

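Apart from HES6, JAK1 and MALAT1, the genes in these opening paragraphs were chosen after their values were seen, and no test was made of them as a group. Several genes of the Notch pathway were measured beside HES6, which encodes a protein related to the Notch target HES1. The ligand gene JAG2 reached 106 ± 2.01 TPM (SD, n = 3), the receptor genes NOTCH3 and NOTCH1 81.4 ± 2.56 and 64.5 ± 2.58, and HES1 45.8 ± 4.73, while HEY1 lay at 7.99 ± 0.757 and the ligand gene DLL4 at 0.391 ± 0.168. DLL3, an inhibitory Notch ligand that marks many neuroendocrine tumours, lay at 21.5 ± 0.206 TPM, with 938, 876 and 936 reads. Another transcription factor gene, ASCL2, reached 17.7 ± 3.56 TPM.

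Among Janus kinase genes, TYK2 was the highest at 44.7 ± 0.306 TPM, followed by JAK2 at 6.17 ± 0.853, JAK1 at 5.52 ± 0.176 and JAK3 at 1.16 ± 0.176. STAT3 reached 74.9 ± 0.941 TPM, against 0.933 ± 0.0281 for STAT6. GSTP1, a detoxification gene often silenced in prostate cancer, lay at 13.1 ± 2.41 TPM. After MALAT1, the long non-coding RNAs with the highest TPM included SNHG19 at 284 ± 11.2, NORAD at 194 ± 6.87 and GATA2-AS1 at 178 ± 1.46. After depletion of ribosomal RNA, mitochondrial ribosomal RNA held 8.16, 29.0 and 6.96 CPM in replicates 1, 2 and 3, so these values do not give its level in the cells. Mitochondrial messenger RNA took 3.29%, 2.87% and 3.33% of reads.

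All tests in the following paragraphs were chosen after the result was seen. The excess of genes varying between libraries was set against the counting of both mates and against GC content. Among genes with 2 to 41 reads, 77.6%, 74.6% and 80.7% of counts were even in replicates 1, 2 and 3, so separate counting of mates may account for part of the excess. With the statistic divided by 2, 17.6% of tested genes still varied, which argues against it as the whole cause. The correlation of replicate 2 minus replicate 3 with GC content across genes (r = −0.646) makes a GC trend another candidate source of part of it, although 8086 genes (38.4%) still varied with that trend alone removed, against 9694 (46.1%) before. After both corrections 9.16% of genes still varied, so what remains is open, and no biological explanation was tested because the libraries form 1 group.

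RN7SK, RMRP, RPPH1, RN7SL1 and SCARNA2, named after their values were seen, are abundant in most human cells and had 0 reads in every library. Each had 100% of its exon bases shared with another annotated gene, and a candidate explanation is reads overlapping more than one gene left out by the counting. Absence of these RNAs from the cells could not be tested, because the 5 genes had 0 unshared exon bases at which a read would have been counted. No biological explanation was tested.

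ETV1 had 12, 12 and 0 reads (0.0518 ± 0.0450 TPM), although the parental LNCaP line is known for a rearrangement that raises its expression. Loss of reads to an overlapping gene is unlikely, since 0% of its exon bases were shared with another gene. The androgen response list lay at the 100th percentile of random lists, but so did the proliferation and chromatin regulator lists. That rank alone therefore cannot decide whether a line without androgen response was used under the C4-2 label. Its member KLK3 reached 1439.7 ± 26.3 TPM, but no line without androgen response was analysed here for comparison. Another luminal line with an androgen response, or loss of ETV1 expression in this stock of C4-2, also stays open and was not tested. No biological explanation was tested.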
